A study of Mus musculus with 12 samples.

How the data were processed

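H3K27me3, the histone mark laid down by Polycomb repressive complex 2, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in hepatocytes isolated from wild-type mouse livers by perfusion and low-speed centrifugation, per the labels' protocols. The series held 12 samples. At postnatal day 14 (P14) there were 4 ChIP and 4 input samples, each set from 2 males and 2 females. At 2 months (M2) there were 2 ChIP and 2 input samples whose sex the labels give as unknown. The labels describe each M2 sample, and no P14 sample, as a re-analysis of another deposited sample, so age and the origin of the samples changed together.

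The deposited data used here were 2 lists of H3K27me3 domains, 1 per age. The sample labels name the same list for every ChIP and input sample of an age, so each list was read as pooled over its replicates. The submitters' processing notes name STAR 2.4.2a, bedtools and the mm9 genome build, without saying what each was used for. The domain caller, its threshold and the way input was used are not given in the sources used here. Each list gave a chromosome, a start and an end. Every start and end was a multiple of 1000 bp, so the authors' domains lie on a grid of 1 kb and no shorter interval can appear. The score column that the authors deposited held 0 for every domain and the name column held a dot, so no height, enrichment or p-value was attached to any domain. No 2 domains of a list overlapped or touched. Read depth is unknown, and no interval that needs it is given.

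Domains were compared on the 1 kb grid with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9. Coordinates are mm9, counted from 1. Covered length is the union of a list's domains. Covered share is that length divided by the span from the first to the last domain of either list on the chromosome. Ratios and shares of covered length carry 95% bootstrap intervals from 1000 resamples of genome blocks of 10 Mb. These intervals describe variation along the genome within this pair of lists, not variation between animals. Domain overlap was counted with bedtools 2.31.1 at a minimum of 1 bp, with exact Clopper-Pearson 95% intervals (scipy 1.17.1) that cover counting error only. The overlap expected by chance was taken from 100 circular rotations of the other list within each chromosome, by at least 1 Mb on the autosomes and X (10 rotations for each alternative). A second displacement, by 50 to 200 kb in either direction, keeps the regional density of domains and was added after the data were seen. Domains of 1 kb cannot lie inside longer domains of their own list, where the other list is denser. Neither displacement keeps this limit, so the displaced overlap of 1 kb domains can lie too high. Sequence inside the span that holds no domain in either list was not masked. For domains of all lengths, this can make the displaced overlap too low and its excess over chance too large. With 1 pooled list per age there was no spread between replicates in the values used, so no test between ages was run and no p-value is given for any difference between ages. The labels also name 1 signal track per age, pooled over its replicates, which was not used here.

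The overlap, displacement and joining code was tested on altered copies of the M2 list. A rotated copy of the M2 list overlapped the M2 list at 44.8% of domains, against a mean of 44.8% over 20 rotations. A kept share of 49.9% of M2 domains was recovered as 49.9%. These outcomes follow from how the copies were made, so they check the code alone. They do not show whether rotation gives a fair chance level for P14 against M2. Joining restored 48737 of 48737 domains that had been split, and the second displacement moved each of 21 chromosomes within its set range.

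The comparisons, the gene lists and the alternatives were fixed before the data were examined. The alternatives were a minimum domain length of 2 kb, joining of domains within 1 kb, the longest 75% of each list (length took the place of the empty score, with ties broken at random from a fixed seed), autosomes alone, lists of equal covered length (the shortest M2 domains dropped until both lists covered the same length, which left M2 domains of 3 kb or more and the P14 list whole), and stricter overlap rules. Genes could not be placed on the domains, because gene positions on mm9 were not used here and the lists carry no gene names. The planned counts of marked genes and the planned gene lists were therefore left out. The rule fixed for that case named the 10 longest domains of each age, the 10 longest stretches covered at only one age, the longest shared stretch of each chromosome, and each chromosome. The ratios for the autosomes and for X, the counts of domains of 50 kb or more, the split by domain length and the windows of 100 kb and 1 Mb were added after the data were seen. Windows start at whole multiples of their size. Windows that did not lie wholly inside the span of a chromosome and windows with no domain at either age were left out.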

Results

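The data comprised 1 list of H3K27me3 domains for P14 hepatocytes, drawn from 4 ChIP and 4 input samples, and 1 list for M2 hepatocytes, drawn from 2 ChIP and 2 input samples. P14 is a stage before weaning and M2 is young adulthood. The series title places the work in the study of how the Polycomb methyltransferases EZH1 and EZH2 act on the liver after birth, and the comparison of the lists addresses where the mark that they deposit lies in hepatocytes at each age. The P14 list held 226035 domains and the M2 list 212874. Each list has no replicate of its own, so every difference below lies between this pair of lists and has no replicate check. Age, the origin of the samples, the number of pooled samples and the sexes on record changed together.

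H3K27me3 domains covered more of the genome at M2 than at P14, and chromosome X stood apart from every autosome. Domains covered 607.9 Mb at P14 and 826.6 Mb at M2, a ratio of 1.36 (95% block bootstrap interval 1.32 to 1.40, 267 blocks). Covered length was higher at M2 on all 21 chromosomes. On the 19 autosomes together the covered share was 22.4% at P14 and 28.8% at M2, a ratio of 1.29 (95% interval 1.26 to 1.31). On chromosome X the covered share was 40.9% at P14 and 80.2% at M2, a ratio of 1.96 (95% interval 1.80 to 2.13, 17 blocks). X holds 6.34% of the total span but carried 29.4% of the net difference of 218.7 Mb.

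Among the autosomes the covered share ran from 17.9% on chromosome 10 to 27.3% on chromosome 11 at P14. The same chromosomes marked the extremes at M2, with 23.9% on chromosome 10 and 32.9% on chromosome 11. The ratio of M2 to P14 was lowest on chromosome 13, at 1.19, and highest on chromosome 16, at 1.47. The 1.96 of chromosome X lay above this range. Chromosome Y, of which the domains span 2.89 Mb, was covered at 12.8% at P14 and 16.2% at M2. The sexes pooled at P14 are known and those at M2 are not, so the values for X and Y cannot be assigned to age.

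**Figure D1:**
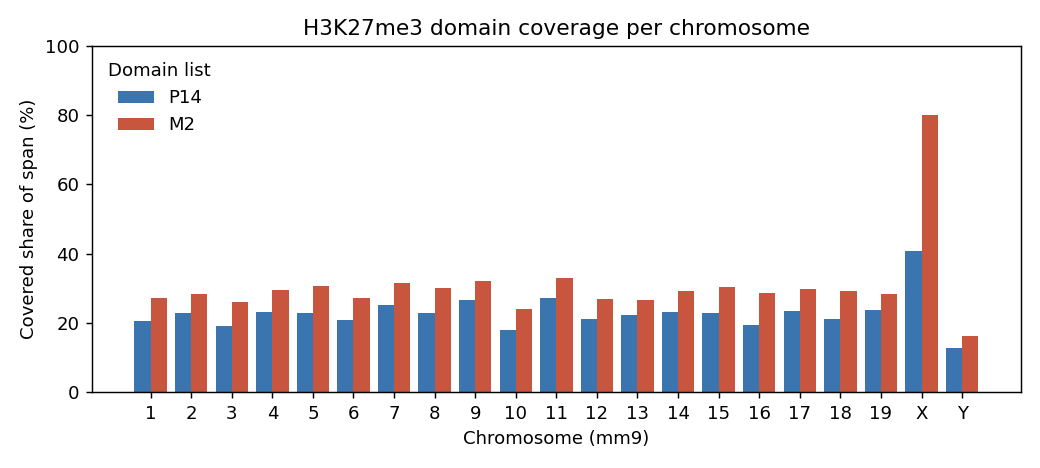
Share of each chromosome's span (percent, mm9) covered by H3K27me3 domains in the P14 list (blue) and the M2 list (red); each bar is 1 pooled list, so there are no error bars. The autosomes lie between 17.9% and 27.3% at P14 and between 23.9% and 32.9% at M2, while X goes from 40.9% to 80.2%.

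M2 domains were fewer but longer. Their number was lower than at P14 on 14 autosomes and on X, higher on 4 autosomes and on Y, and equal on chromosome 15. The mean domain length was 2.69 kb at P14 and 3.88 kb at M2, while the median was 2 kb at both ages. Single grid bins of 1 kb made up 44.9% of P14 domains and 23.3% of M2 domains. Domains of 50 kb or more numbered 129 at P14 and 544 at M2. On the autosomes these counts were 123 and 354, and on X they were 6 and 190. Domains of 20 kb or more held 8.23% of the covered length at P14 and 17.6% at M2. On X that share was 8.14% at P14 and 39.3% at M2. Joining domains within 1 kb of each other gave 433 and 1504 domains of 50 kb or more, so the absolute counts depend on how the authors' domains are broken, while the M2 count stayed the higher.

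The 10 longest P14 domains measured 111 to 237 kb, and none of them lay on X. The longest was on chromosome 8 from 12730001 to 12967000 (237 kb), and a second stretch of 207 kb lay nearby from 11986001 to 12193000. They were followed by chromosome 15 from 102715001 to 102903000 (188 kb), chromosome 4 from 136680001 to 136855000 (175 kb), chromosome 11 from 96093001 to 96249000 (156 kb), chromosome 6 from 52095001 to 52233000 (138 kb), chromosome 7 from 75094001 to 75223000 (129 kb) and chromosome 2 from 74476001 to 74604000 (128 kb). The last of the 10 were on chromosome 4 from 129619001 to 129734000 (115 kb) and on chromosome 19 from 56897001 to 57008000 (111 kb). M2 domains covered at least 92.0% of each of the 10, and 4 of them were covered in full. The lowest value, 92.0%, belonged to the 237 kb domain on chromosome 8.

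The 10 longest M2 domains measured 227 to 428 kb, and 7 of them lay on X. The longest 2 were on chromosome 8 from 12194001 to 12622000 (428 kb) and on chromosome 7 from 74988001 to 75393000 (405 kb). P14 domains already covered 96.7% and 95.3% of these stretches, in shorter pieces. The third autosomal member was on chromosome 6 from 52048001 to 52285000 (237 kb), which contains the 138 kb P14 domain of that chromosome and was covered at 91.1% at P14. The 7 domains on X included 96174001 to 96455000 (281 kb), 145822001 to 146100000 (278 kb) and 99075001 to 99350000 (275 kb), where P14 domains covered 88.3%, 77.0% and 88.0%. The lowest P14 share among the 10 was 75.8%, on X from 12024001 to 12251000.

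The next comparison asked how far the domains lay in the same places at both ages. Broad P14 domains were mostly covered at M2, broad M2 domains less fully at P14, and the shortest autosomal domains overlapped by number a little more often than under either displacement. Domains at both ages covered 375.2 Mb, P14 alone 232.6 Mb and M2 alone 451.3 Mb. The shared part was 35.4% of the length covered at either age (Jaccard index, 95% interval 33.7 to 37.0), against 17.1% on average over 100 rotations (range 16.8 to 17.5). A displacement of 50 to 200 kb gave 22.4% (range 21.6 to 23.0). By number, 55.4% of P14 domains overlapped an M2 domain (125153 of 226035, exact 95% interval 55.2 to 55.6), against 41.9% over rotations and 45.0% over shifts of 50 to 200 kb. In the other direction 49.4% of M2 domains overlapped a P14 domain (105146 of 212874, exact 95% interval 49.2 to 49.6), against 39.1% and 40.2%. These exact intervals treat neighbouring domains as independent. The block bootstrap interval for the share of P14 length covered at M2, 61.7%, was far wider, at 59.5 to 63.8. Other rules gave other shares, with 49.7% for P14 and 32.3% for M2 where the overlap had to reach 50% of the domain counted. Where it had to reach 50% of both domains, the shares were 23.7% and 25.1%. That rule counts almost the same pairs from each side, so the order of its shares follows from the smaller number of M2 domains. Dropping the shortest M2 domains until both lists covered the same length gave 38.7% and 74.0%, a shift given by construction.

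The overlap depended on domain length. On the autosomes 30.9% of the 95892 P14 domains of 1 kb overlapped an M2 domain, against 28.7% over rotations (range 28.2 to 29.2) and 28.3% over shifts. After domains within 1 kb were joined it was 30.3%, against a rotated mean of 30.4%. Displaced levels can lie too high for 1 kb domains, which cannot lie inside longer domains of their own list. They can also lie too low, since sequence without domains was not masked. For P14 domains of 6 to 10 kb, 72.9% of the length was covered at M2, against 29.1% over rotations and 43.2% over shifts. For those of 21 to 50 kb the figures were 93.1%, 29.5% and 51.9%, and for the 118 domains over 50 kb they were 97.2%, 29.4% and 62.6%. M2 domains showed the same dependence on length, with 23.4% of the length of 1 kb domains covered at P14, against 22.2% over rotations and 18.8% over shifts (range 18.4 to 19.4). For M2 domains over 50 kb it was 88.2%, against 22.9% and 56.1%. After joining within 1 kb, the overlap of autosomal M2 domains of 1 kb was 23.0%, against a rotated mean of 23.3%. Of the 1418 autosomal P14 domains of 20 kb or more, M2 domains covered at least 90% of the length in 1102 (77.7%). Under 50% was covered in 19, and 1 had no M2 domain at all. The reverse share was lower. Of the 2707 autosomal M2 domains of 20 kb or more, P14 domains covered at least 90% of the length in 883 (32.6%) and under 50% in 123. On X this was so for 54 (3.72%) and 583 (40.2%) of 1451 M2 domains.

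**Figure D2:**
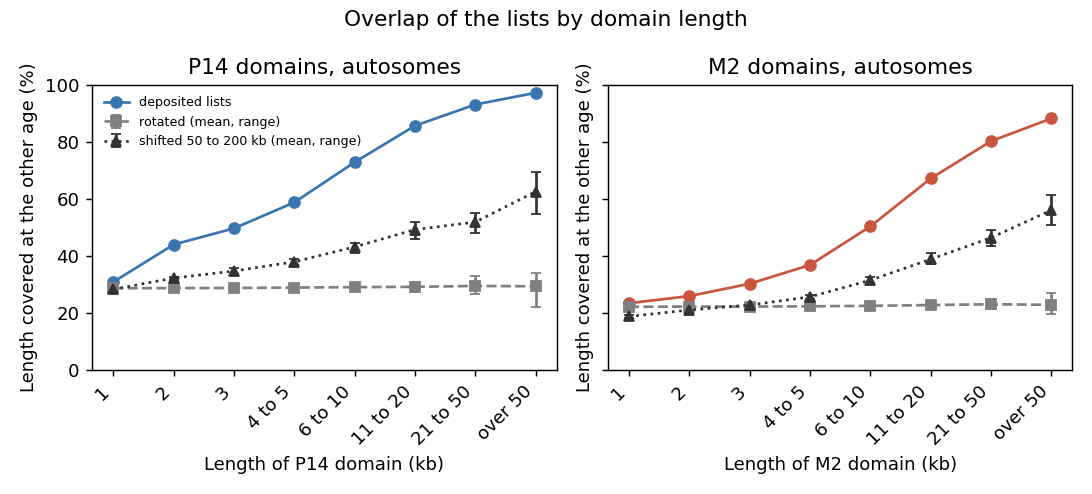
Share of the length of autosomal domains (percent) covered by the list of the other age, by domain length in kb, for P14 domains (left) and M2 domains (right). Circles are the deposited lists, squares the mean over 100 rotations and triangles the mean over 100 shifts of 50 to 200 kb, with bars from lowest to highest; P14 domains go from 30.9% at 1 kb to 97.2% above 50 kb, rotations from 28.7% to 29.4% and shifts from 28.3% to 62.6%.

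On X the overlap of P14 domains by number, 94.5%, lay above rotations and shifts alike (both 89.5%), while that of M2 domains depended on the displacement. M2 domains covered 92.3% of the P14 length on X, against 80.3% over rotations and 83.9% over shifts. The share of M2 domains on X that overlapped a P14 domain, 72.6% of 14369, lay below the 75.7% of rotations (range 73.2 to 77.1) and above the 71.2% of shifts (range 70.6 to 71.9). For M2 domains of 1 kb it was 29.7%, below the 41.0% of rotations and within the range of shifts (27.8 to 33.9). The limits given above for displaced levels hold here too. By length, P14 domains covered 47.1% of the M2 domains on X, against 40.8% over rotations and 42.8% over shifts.

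Long M2 domains often overlapped several P14 domains. Of the 2707 autosomal M2 domains of 20 kb or more, 87.0% overlapped at least 2 P14 domains, and the highest number was 19. Of the 1418 P14 domains of that length, 48.7% overlapped at least 2 M2 domains, with a highest number of 9. On X, 1414 of the 1451 M2 domains of 20 kb or more overlapped at least 2 P14 domains. These counts were not set against displaced lists. A long domain can meet several domains of a dense list wherever it lies, so the counts do not show that P14 domains merged.

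The longest stretch covered at both ages was taken for each chromosome, and the highest of these was on chromosome 4 from 136680001 to 136854000 (174 kb). On the next chromosomes it measured 171 kb on chromosome 8 from 12022001 to 12193000, 168 kb on chromosome 15 from 102715001 to 102883000, 154 kb on chromosome 11 from 96093001 to 96247000 and 138 kb on chromosome 6 from 52095001 to 52233000. In all, 11 of the 21 chromosomes held a shared stretch of 100 kb or more. On chromosome X the longest measured 72 kb, from 45753001 to 45825000, and on 6 autosomes it was under 60 kb, with 38 kb on chromosome 10 as the shortest among autosomes. On Y it was 4 kb.

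Stretches covered at only one age were short, and those of M2 reached further than those of P14. The 152875 stretches covered at P14 alone had a median of 1 kb, and 74 of them were 10 kb or longer. The 220617 stretches covered at M2 alone had a median of 2 kb, and 718 were 10 kb or longer, 254 of them on autosomes. The longest P14-only stretch was on chromosome 1 from 182890001 to 182910000 (20 kb). It was followed by 18 kb on chromosome 19 from 37763001 to 37781000 and 18 kb on chromosome 9 from 74694001 to 74712000. With 50 kb added on each side, the chromosome 9 region was covered at 22.9% at P14 and 0.847% at M2. Each flanked region includes the stretch itself, so a large part of its contrast is fixed by the choice of the stretch. On chromosome 9, and in the chromosome 18 region given next, the stretch makes up most of the P14 cover. A 16 kb stretch on chromosome 18 from 20773001 to 20789000 gave 20.7% at P14 and 2.59% at M2 over its flanked region. A 17 kb stretch on chromosome 15 from 102926001 to 102943000 lay beyond the end of the 188 kb domain of that chromosome, and its flanked region remained covered at 53.8% at M2 against 83.8% at P14. None of the 10 longest P14-only stretches was on X.

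Of the 10 longest M2-only stretches 5 lay on X. The longest were on X from 92123001 to 92174000 (51 kb), on chromosome 11 from 99303001 to 99345000 (42 kb) and on X from 120149001 to 120191000 (42 kb). With 50 kb on each side, the chromosome 11 region was covered at 26.8% at P14 and 95.1% at M2. The flanked regions again include the stretch itself, which fixes part of the contrast. Stretches of 26 kb lay on chromosome 5 from 132925001 to 132951000, with 12.7% at P14 and 90.5% at M2 over the flanked region, and on chromosome 6 from 115293001 to 115319000, with 10.3% and 77.0%. A 23 kb stretch on chromosome 2 from 54027001 to 54050000 had 9.76% at P14 and 46.3% at M2 over its flanked region, and a 22 kb stretch on chromosome 7 from 149746001 to 149768000 had 38.5% and 75.4%.

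Larger regions also differed between the lists in both directions. The windows named here were chosen after their values were seen. In windows of 100 kb on the autosomes, 15127 of 23937 were covered more at M2 and 8060 more at P14, with a median difference of 5 percentage points. A difference of 30 points or more was seen in 816 windows towards M2 and in 57 towards P14. The highest differences towards M2 were on chromosome 1 from 121000001 to 121100000 (8% at P14, 90% at M2), chromosome 11 from 99300001 to 99400000 (14% and 94%) and chromosome 5 from 132900001 to 133000000 (12% and 91%). Those towards P14 were on chromosome 12 from 118700001 to 118800000 (76% at P14, 26% at M2), chromosome 12 from 101700001 to 101800000 (61% and 12%), chromosome 11 from 53800001 to 53900000 (73% and 25%) and chromosome 18 from 24900001 to 25000000 (83% and 35%). Adjacent windows on chromosome 15 from 77300001 to 77500000 had 48% and 49% at P14 against 4% and 2% at M2. Adjacent windows on chromosome 7 from 66600001 to 66800000 had 61% and 53% at P14 against 14% and 8% at M2.

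**Figure D3:**
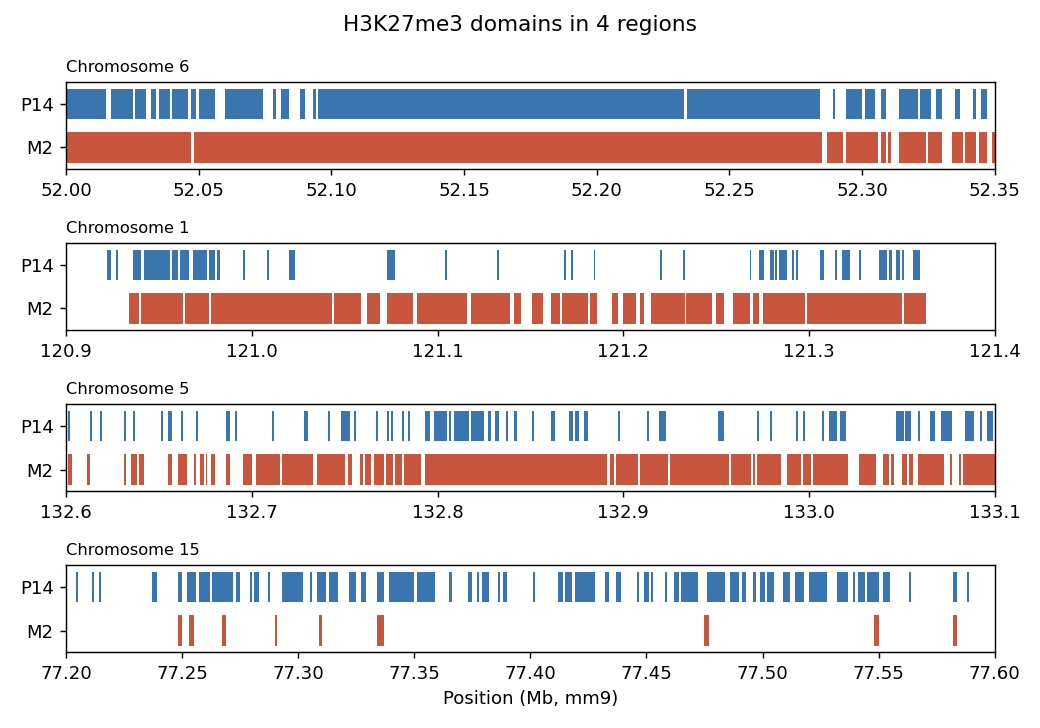
H3K27me3 domains of the P14 list (blue, upper row) and the M2 list (red, lower row) in 4 regions, by position in Mb (mm9); each block is 1 domain. Domains cover 82.0% and 94.9% of the chromosome 6 region at P14 and M2, 18.4% and 73.8% of the chromosome 1 region, 23.4% and 74.4% of the chromosome 5 region, and 43.8% and 4.25% of the chromosome 15 region.

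At 1 Mb, 1841 of 2385 autosome windows were covered more at M2 and 535 more at P14. The covered shares of these windows at the 2 ages correlated across windows, which are not independent replicates, with a Spearman rho of 0.730 and a Pearson r of 0.839. The windows with the strongest difference towards P14 were on chromosome 4 from 60000001 to 61000000 (25.8% at P14, 5.4% at M2), chromosome 14 from 29000001 to 30000000 (30.3% and 11.1%) and chromosome 17 from 11000001 to 12000000 (22.8% and 5.2%). The neighbours on chromosome 4 from 61000001 to 62000000 (30.8% and 18.1%) and on chromosome 17 from 12000001 to 13000000 (41.2% and 29.2%) were also lower at M2. The highest autosomal differences towards M2 were on chromosome 11 from 92000001 to 93000000 (15.7% and 45.8%), chromosome 1 from 121000001 to 122000000 (8.4% and 37.9%) and chromosome 15 from 4000001 to 5000000 (18.6% and 47.9%).

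On X all 162 windows of 1 Mb were covered more at M2, by 7.4 to 55.4 percentage points, with a median of 40.9. The highest difference was from 80000001 to 81000000, with 28.2% at P14 and 83.6% at M2. The lowest was from 31000001 to 32000000, with 19.5% and 26.9%. X windows at M2 reached 70% or more in 144 of 162 cases, against 23 of 2385 autosome windows.

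**Figure D4:**
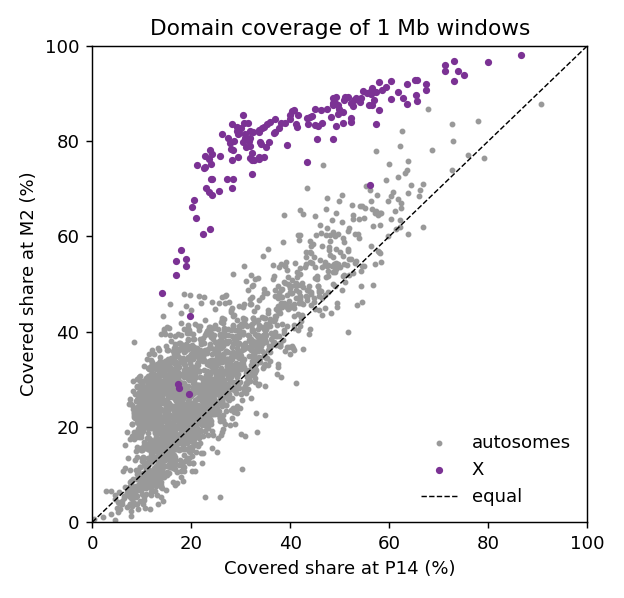
Covered share (percent) of windows of 1 Mb at P14 (x axis) and M2 (y axis); each point is 1 window, grey for autosomes and purple for X, and the dashed line marks equal shares. All 162 X windows lie above the line, and 1841 of 2385 autosome windows do.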

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

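The tests of the alternatives on the autosome and X ratios, on the counts of domains of 50 kb or more, on the named stretches and with displaced lists were chosen after the data were seen. In every alternative run, the X ratio stayed above the autosome ratio, and the overlap of the domains of all lengths and the Jaccard index stayed above their rotated means. With a minimum of 2 kb the ratio of covered length was 1.53 overall and 1.45 on the autosomes, and P14 and M2 overlap shares were 68.3% and 44.3%. Joining within 1 kb gave a Jaccard index of 37.4%, shares of 54.8% and 51.1%, and 433 and 1504 domains of 50 kb or more. The longest 75% of domains gave an autosome ratio of 1.31 and shares of 57.6% and 50.7%. Autosomes alone gave a ratio of 1.29, shares of 51.6% and 47.7%, and 354 M2 domains of 50 kb or more. Equal covered length, reached by dropping M2 domains under 3 kb and part of those of 3 kb, gave shares of 38.7% and 74.0%, a shift that removing short M2 domains gives by construction. With it the autosome ratio was reversed, at 0.894, also by construction, while X stayed at 1.86. The overlap of autosomal 1 kb domains came close to or below its rotated mean. It was 16.4% against 19.8% for P14 with equal covered length, where the rotated M2 list lacked short domains too. For P14 it was 26.4% against 26.3% with the longest 75%. After joining it was 30.3% against 30.4% for P14 and 23.0% against 23.3% for M2. Rotated levels can lie too high or too low for 1 kb domains, as described above. Requiring 50% of a domain's own length gave 49.7% and 32.3%, and a reciprocal 50% gave 23.7% and 25.1%. The order of the reciprocal shares follows from the smaller number of M2 domains. Where the setting itself does not fix the change, the cause was not tested. For the longest domains 30 alternative values moved. The others were in part fixed by the settings, as were those of one-age and shared stretches, and show nothing about stability. The counts of marked genes were not run, since gene positions on mm9 were not used here. No replicate could be left out, and no paired analysis was possible because each age has 1 pooled list. Read depth, which can affect how many short domains are called, is unknown.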

Other observations

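The tests of the list-wide depth or threshold difference, of chromosome Y, of the 1 kb domains, of the Hox chromosomes and of the windows within range in both lists were chosen after the results were seen, and those of the spread of the X difference and of matched covered share before.

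A few parts of X did not follow the rest of the chromosome. Of 1635 X windows of 100 kb, 7 were covered less at M2 than at P14, with differences from -9 to -1 percentage points. They included 100900001 to 101000000 (56% at P14, 47% at M2), 100700001 to 100800000 (3% and 1%) and 12800001 to 12900000 (57% and 51%). Another 3 of the 7 lay close together, from 30800001 to 30900000 (18% and 15%), from 32100001 to 32200000 (19% and 16%) and from 32200001 to 32300000 (2% and 1%). Each percentage point is 1 bin of 1 kb in such a window, and the 7 are the lowest of 1635. No replicate check exists for differences this small. At 1 Mb the lowest M2 cover on X was found from 31000001 to 32000000 (19.5% at P14, 26.9% at M2), from 4000001 to 5000000 (17.6% and 28.2%) and from 30000001 to 31000000 (17.4% and 29.1%).

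Chromosome X had a far higher ratio of M2 to P14 cover than the autosomes. A depth or threshold difference that raises windows of equal P14 cover alike is argued against. X windows of 1 Mb lay a median of 35.9 percentage points (quartiles 28.9 and 43.4) above autosome windows within 2.5 points of the same P14 cover. Of 154 matched X windows, 149 lay above every matched autosome window. Cover holds no signal below the calling threshold, so a list-wide difference stays possible if X held more such signal at P14. A few strong regions do not carry the higher X ratio, since the highest-gaining 25% of X windows held 32.7% of the net difference. A larger share of female X chromosomes in the M2 pool is a candidate explanation, because the inactive X of females is rich in H3K27me3, but the sex of the M2 animals is not recorded. Chromosome Y, which all-female M2 samples would lack, had an M2 to P14 ratio of 1.26, and M2 domains covered 46.6% of the P14 length on Y. The longest Y domains were 7 kb at M2 and 12 kb at P14, a list that includes males, so their length decides nothing. Reads from similar sequence on other chromosomes, and how the caller treats sequence without reads, were not tested, so all-female M2 samples cannot be told apart from mixed ones. Age and the separate origin of the M2 libraries remain open too.

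The shortest autosomal P14 domains overlapped M2 domains little more often than under rotation. The excess was 2.21 percentage points for autosomal P14 domains of 1 kb, against 18.2 points for those of 2 kb and 25.4 points for those of 3 kb. On X it was higher at 1 kb, at 6.03 points (86.0% observed, 80.0% over rotations). A 1 kb domain cannot lie inside a longer domain of its own list, and broad P14 domains were mostly covered at M2. Rotation does not keep this limit, so it can understate the excess at 1 kb. It also runs over sequence that holds no domain in either list, which can overstate the excess at every length. Overlap by number nears its ceiling in long domains, where the excess in covered length was 63.6 points over rotation (21 to 50 kb; 93.1% observed, 51.9% over local shifts). Calls of 1 kb close to the calling threshold are a candidate explanation, but a low excess at 1 kb only restates the pattern, so it cannot be told apart from short domains that differ between the ages in the cells.

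The most frequent autosomal domain length was 1 kb at P14 and 2 kb at M2. The higher cover at M2 alone is argued against: in autosome windows of 1 Mb covered at 20% to 30%, picked for each list on its own (619 at P14, 841 at M2), 1 kb domains made up 43.5% of P14 domains and 28.8% of M2 domains, a difference of 14.7 percentage points. In the 281 windows within that range in both lists the shares were 42.5% and 20.1%. A difference between the lists in how signal was smoothed or called, or in library fragment length, could give this and stays open, as does age.

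Of the 8 longest P14 domains, 4 lay on chromosomes 2, 6, 11 and 15, which carry the Hox clusters, classical Polycomb targets. A candidate explanation is that these domains mark the clusters. A one-sided exact permutation over 3876 choices of 4 chromosomes gave p = 0.0137 for the rank of their longest P14 domain, but it ranks the same domains that prompted the idea, so this p is no evidence for it. Gene positions on mm9 were not used here, and the identity of the domains stays open. M2 domains covered at least 98.4% of each of the 4 domains on these chromosomes. Among the rest of the 8, the lowest value was 92.0%, on chromosome 8, and the others reached 99.4% or more.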
